A study of Capra hircus with 6 samples.

How the data were processed

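Skin with hair follicles from black-coated and from white-coated regions was compared in 6 libraries of total RNA from crossbred goats, 3 per group. The group of each sample was taken from the region named in its label. The replicate numbers were taken from the titles.

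The authors deposited read counts per transcript, per the file headers, and FPKM values (fragments scaled by transcript length and library size) for the same transcripts, per the file headers. The submitters' processing notes name Bowtie2 2.0.6, HISAT2 and Cufflinks, without saying which step each was used for. The program that counted the reads, the genome build, the annotation and whether strand was used are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. Ribosomal RNA was depleted and libraries were made by standard Illumina protocols, per the labels' protocols.

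The table held 53266 transcript rows. Rows without a gene name (189) and rows of transfer RNA (1776) were left out of library sizes and tests: the first held between 0.00376% and 0.0675% of a library's summed rows and the second between 0.00767% and 0.0126%. Transcripts of most genes carried nearly the same count, the median ratio of the lowest to the highest row being 99.1% over 6588 genes and at least 90% in 74.4% of them, so the rows of a gene were not summed and the row with the largest total stood for the gene. This gave 26952 genes, 10582 of them with a placeholder name. Of the columns with values per sample, 0 were left unused.

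Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM scaling, robust dispersion and the robust quasi-likelihood test of black over white, with Benjamini-Hochberg adjustment over all genes kept and calls at an adjusted p of 0.05. The SE of a log2 fold change was its size divided by the square root of the F statistic. TMM factors ran from 0.872 to 1.12. The biological coefficient of variation was 37.3%. Principal components and correlations used log2 CPM with a prior count of 1.

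Gene lists of pigment cells, hair follicle, epidermis, glands, position, other cell types and stress were fixed before the data were examined, as were the main design and the alternatives not named as added. Of their members 56 were found through the gene description where the symbol was absent. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry. The erythroid list and the list of the mitochondrial genome had too few tested members, and a list of hair keratins and keratin-associated proteins by description was added after the data were seen (93 tested, 43 with a higher mean in black-coated skin, camera p = 3.49e-04 downward, and p = 0.585 with an estimated correlation; without black replicate 1 camera placed it upward, p = 3.99e-19).

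The rule for named genes took called members of the melanin and melanocyte regulator lists, a fixed set of pigment genes whether called or not, the 10 largest changes per direction among called genes with non-overlapping groups and a mean of at least 1 CPM, and up to 4 called members of each other list. Since 0 genes were called, the genes named by size were taken at an unadjusted p under 0.01 in place of a call, and list members are named where they passed over their list alone; both choices were made after the values were seen. A gene with 0 reads in a group was given a floor of 3 counts over the group. Ratios resting on 1 read have an exact 95% interval.

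Alternatives were other scalings (DESeq2's size factor method, upper quartile, library totals, and TMM without keratin and muscle genes), no filter, a filter of at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), a minimum mean FPKM of 1, an adjusted p of 0.01, a minimum log2 fold change of 1, thinning to the smallest library, and leaving out each library in turn. Added after the data were seen were the median or mean transcript row per gene, each transcript row as its own unit, and limma-voom with library quality weights. Neighbouring genes were taken from the ARS1.2 assembly, matched through transcript identifiers for 15609 tested genes. Only chromosome and gene order were used from it, and no distances.

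The test was checked on simulated counts drawn from the means, dispersions and library sizes of the 6 libraries for 15779 genes, with 50 genes changed at each fold. At 2-fold 8% were called, at 4-fold 60%, at 16-fold 88% and at 64-fold 100%, with 15 unchanged genes among 156 calls. A planted list of 18 genes at 4-fold had 13 called over all genes and 16 over the list alone. Simulated without black replicate 1, on 16023 genes, the shares were 22%, 78%, 98% and 100%, with 22 unchanged genes among 189 calls. Genes were drawn independently and no simulated library stood apart from its group. The shares therefore do not carry over to the real libraries, where black replicate 1 stood apart. Tables were prepared with pandas 2.3.3 and plots drawn with matplotlib 3.10.9.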

Results

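RNA was sequenced from goat skin that still held its hair follicles, after removal of ribosomal RNA, in a cross of Boer and Macheng Black goats whose head is black and whose body is white. There were 3 libraries from black-coated skin (black replicates 1 to 3) and 3 from white-coated skin (white replicates 4 to 6). The comparison asked which transcripts differ between skin bearing black hair and skin bearing white hair. The body site of each sample is not given, so differences of coat colour cannot be told apart from differences of site. The labels do not say how many goats gave the 6 samples, so p-values measure only the spread between these samples, which may be partly technical. LOC108634721, described as Y-linked, had 934, 801 and 767 reads in the white libraries and 1, 688 and 0 in black replicates 1, 2 and 3, so the black libraries did not all come from the same animal. The comparison of coat colours is therefore partly one of libraries with and without Y-linked reads. As far as these reads show it, it is thus partly one of the sex of the animals. Reads assigned to named genes numbered 12648764, 16005583 and 22084569 in black replicates 1, 2 and 3, and 17260180, 17028569 and 14679108 in white replicates 4, 5 and 6. Of 26952 genes, 15779 had enough reads to be tested, 2512 of them with a placeholder name. Levels are given in CPM, read counts relative to the scaled library size, as mean ± SD with n = 3 per group, and log2 fold changes are black over white with their standard error (SE).

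Of the 30 gene lists tested, the melanin genes had the median log2 fold change farthest from 0 between black- and white-coated skin. Of the 18 listed melanin enzymes and melanosome proteins 14 could be tested, and all 14 had a higher mean in black-coated skin, with a median log2 fold change of 5.07. The median was also 5.07 with the 2 genes that had 0 white reads set at their bounds. TYR, the tyrosinase that catalyses the rate-limiting step of melanin synthesis, stood at 25.1 ± 21.5 CPM in black-coated skin and had 0 reads in white-coated skin against 1438, at least 407-fold higher with a floor of 3 counts over the white group. TYRP1, which acts later in eumelanin synthesis, stood at 212 ± 180 CPM against 0.0858 ± 0.0484, and PMEL, which forms the fibrils on which melanin is laid down, at 330 ± 272 against 3.02 ± 0.941, 109-fold by the ratio of means. DCT, another enzyme of eumelanin synthesis, stood at 36.8 ± 31.3 CPM against 1.84 ± 0.714, a ratio of 20.02.

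Adjusted over the list alone, 9 of the 14 melanin genes passed edgeR's quasi-likelihood test, all higher in black-coated skin: TYRP1, TRPM1, MLANA, PMEL, SLC24A5, SLC45A2, DCT, TYR and GPR143. By limma-voom 1 member, MLANA, passed over the list alone, and the other settings gave 7 to 13. Adjusted over all genes tested, 0 members passed in edgeR and 9 in DESeq2. MLANA, a melanosome protein, had 937 reads in black-coated skin and 0 in white-coated skin, at least 278-fold higher. SLC24A5, an ion exchanger of the melanosome, had 552 reads against 1. The ratio of reads summed per group and scaled to library size was 526, with a 95% counting interval from 94.0 to 20806. By the ratio of means it was 490-fold. TRPM1, a melanocyte cation channel, stood at 39.5 ± 37.9 against 0.162 ± 0.114 CPM, and SLC45A2, a melanosome transporter, at 20.6 ± 17.5 against 0.360 ± 0.214. The groups did not overlap for these genes except GPR143, whose level in black replicate 1 was 0.355 CPM, below the white range of 0.425 to 0.854. GPR143 did not pass over the list alone without white replicate 4 (adjusted p = 0.0519), 5 (0.0627) or 6 (0.0650). Black replicate 1 had the lowest level of the black libraries for each of these 9 genes, with TYR at 1.06, TYRP1 at 10.3 and PMEL at 15.7 CPM, against 31.7, 269 and 476 in black replicate 2. Black replicates 2 and 3 also differed for TRPM1 (32.1 and 80.5 CPM) and DCT (36.2 and 68.4 CPM). Intervals and floors cover counting error only. As a set, the melanin genes passed camera with a preset correlation (adjusted p = 1.18e-37), while their adjusted p was 0.192 with an estimated correlation.

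**Figure D1:**
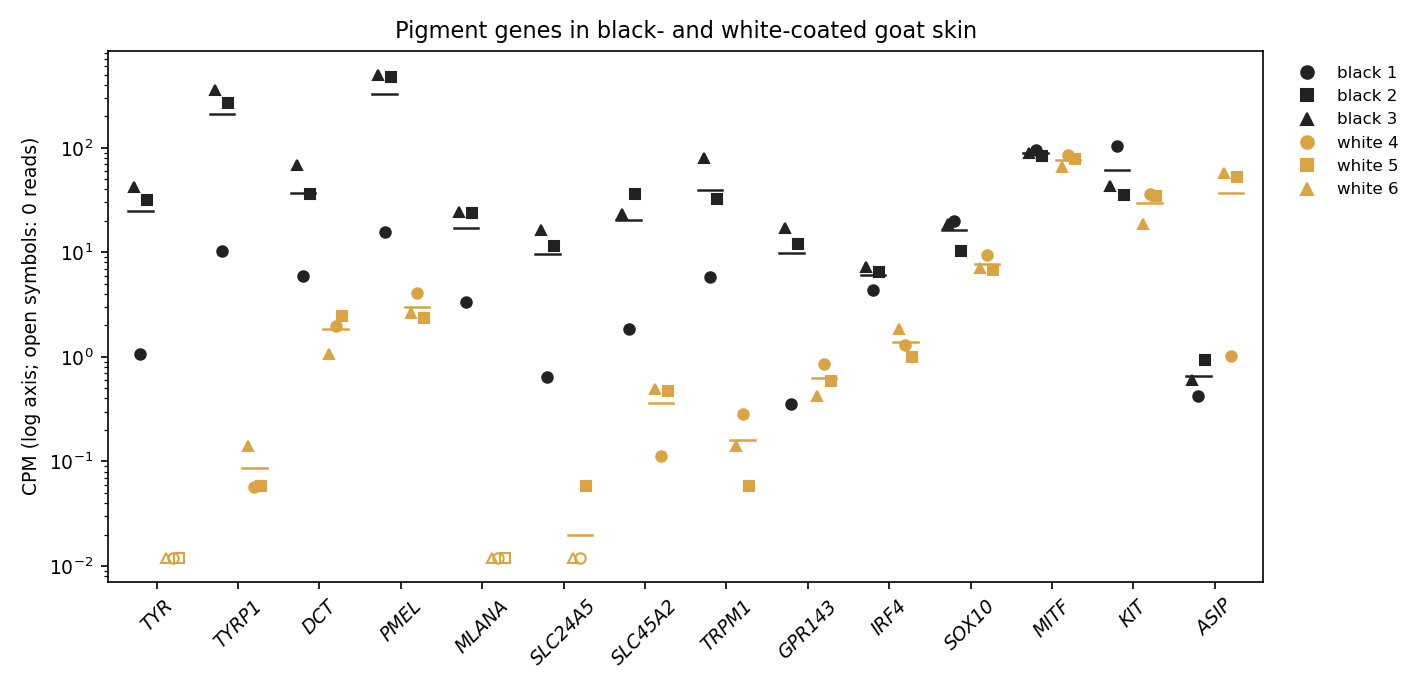
Scaled CPM (log axis) of pigment genes in each library of black-coated and white-coated skin; points are single libraries, horizontal bars are group means, no error bars are drawn, and open symbols mark 0 reads at a fixed level, with no bar for a mean of 0. TYR and MLANA had 0 reads in the 3 white libraries, and black replicate 1 lies below the other black libraries for PMEL, TYRP1 and TYR.

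The regulators that set up and maintain melanocytes differed far less than the melanin genes. Of 12 tested regulators, 1 passed adjusted over the list alone: IRF4, a transcription factor that activates TYR, stood at 6.005 ± 1.503 CPM in black-coated and 1.38 ± 0.427 in white-coated skin (log2 fold change 2.12, SE 0.40, adjusted p = 0.0136 over the list alone). IRF4 did not pass over the list alone without black replicate 3 (adjusted p = 0.0580) or without white replicate 4 (0.0803) or 5 (0.0887). SOX10, another of the regulators, stood at 16.3 ± 5.25 against 7.76 ± 1.52 CPM (log2 fold change 1.07, SE 0.32). Its groups did not overlap, but it did not pass (edgeR adjusted p = 0.0719 over the list alone). MITF, the transcription factor that governs the melanocyte lineage, stood at 89.3 ± 6.67 against 76.6 ± 9.70 CPM (log2 fold change 0.22, SE 0.17), and the groups overlapped. KIT, the receptor that melanoblasts and mast cells share, stood at 60.9 ± 37.8 against 29.7 ± 9.53 CPM (log2 fold change 1.03, SE 0.46). In black replicate 1 KIT stood at 104 CPM, and the mast cell protease CPA3 at 118 CPM against a range of 6.45 to 38.1 in the other 5 libraries. Camera placed the regulators higher in black-coated skin (adjusted p = 0.0313), as it did 27 genes of melanosome biogenesis and transport (adjusted p = 0.0123), none of which passed alone. With an estimated correlation the adjusted p was 0.351 for the regulators and 0.323 for melanosome biogenesis. Without black replicate 3 the adjusted p was 0.492 for the regulators and 0.0897 for melanosome biogenesis, and the latter was 0.0503 without black replicate 2 and 0.119 without white replicate 6. MC1R was not analysed here.

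Among signals that reach melanocytes from other skin cells, ASIP had the largest difference. ASIP, the agouti protein that turns melanocytes from black to yellow pigment, stood at 0.426, 0.932 and 0.606 CPM in black replicates 1 to 3 and at 1.02, 52.1 and 56.8 CPM in white replicates 4 to 6 (log2 fold change -5.80, SE 1.36), with an adjusted p of 0.073 over the list alone. Without white replicate 4, ASIP passed over all genes (log2 fold change -6.37, edgeR adjusted p = 0.0387). KITLG, the ligand of KIT, stood at 62.5 ± 29.0 against 89.96 ± 34.2 CPM (log2 fold change -0.53, SE 0.44). Of 19 tested signals, 13 had a lower mean in black-coated skin and 0 passed over the list alone. Camera placed the list lower in black-coated skin (adjusted p = 0.00523, and 0.323 with an estimated correlation).

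Genes of the cornifying epidermis were lower in black-coated skin in 28 of 29 tested members, with a median log2 fold change of -0.71. Adjusted over the list alone 4 of them passed in edgeR, and over all genes 0 passed in edgeR and 6 in DESeq2, all 6 lower in black-coated skin. ASPRV1, a protease of the upper epidermis that processes filaggrin, stood at 52.4 ± 10.4 CPM in black-coated and 172 ± 39.5 in white-coated skin. LOR, the cornified envelope protein loricrin, stood at 2.84 ± 0.641 against 17.0 ± 10.98 CPM, KPRP at 8.67 ± 2.28 against 24.1 ± 6.42, and KRT10, a keratin of suprabasal keratinocytes, at 51.0 ± 34.9 against 398 ± 266. Camera placed the list lower in black-coated skin (adjusted p = 3.24e-22), with an adjusted p of 0.323 with an estimated correlation. Leaving out white replicate 4, white replicate 5 or black replicate 2 left 1 member past the test over the list alone, and leaving out white replicate 6 left 7. ASPRV1 passed without each library in turn, and KRT10 also did not pass without black replicate 3 (adjusted p = 0.0521). The level of this list was also lowest in black replicate 1, at -1.79 log2 units relative to the mean of the other 5 libraries. Relative to the mean of all libraries, the list stood at -1.49, -0.61 and 0.23 in black replicates 1 to 3. It stood at 1.06, 0.61 and 0.20 in white replicates 4 to 6, so the groups overlapped on the list.

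Skin glands gave mixed results. Of 19 tested sweat gland genes 2 passed adjusted over the list alone, both higher in black-coated skin: MUCL1, a small secreted mucin, at 3046, 1721 and 395 CPM in black replicates 1 to 3 against 46.8 ± 38.4, and LTF, the antimicrobial protein lactotransferrin, at 175, 14.8 and 19.7 CPM against 1.38 ± 0.711. The log2 fold change of LTF was 5.67, and 3.66 without black replicate 1. Neither gene passed over the list alone without white replicate 5 (adjusted p = 0.0872 for both) or 6 (0.0735 for both), nor LTF without white replicate 4 (0.0680) or MUCL1 without black replicate 1 (0.0511). The sweat gland list passed camera (adjusted p = 0.0251, and 0.323 with an estimated correlation), but not without black replicate 3 (0.364), white replicate 5 (0.0571) or white replicate 6 (0.0920). Of 30 sebaceous gland and lipid synthesis genes 1 passed over the list alone: SCD, the stearoyl-CoA desaturase, at 233 ± 56.8 CPM against 98.5 ± 13.5, which did not pass without black replicate 3 (adjusted p = 0.0612) or without white replicate 4 (0.207), 5 (0.151) or 6 (0.283). The sebaceous list as a whole did not pass camera (adjusted p = 0.143), but was lower in black-coated skin and passed without black replicate 1 (0.0413), black replicate 3 (0.0454) or white replicate 4 (0.0288), and turned without black replicate 2 (0.997).

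Black replicate 1 stood apart in markers of the hair shaft and of immune cells. The hair shaft list stood at -3.12 log2 units in black replicate 1, relative to the mean of all libraries, and between 0.37 and 0.87 in the other 5. TCHH, the inner root sheath protein trichohyalin, stood at 350 CPM in black replicate 1 against 3624 to 7273 elsewhere, and KRT25, an inner root sheath keratin, at 272 against 4367 to 5604. The macrophage list stood at 1.59, the list of B and plasma cells at 1.61, that of T and NK cells at 1.31 and that of mast cells at 2.32 log2 units in black replicate 1, each the highest of the 6 libraries. Camera placed 28 hair shaft genes (adjusted p = 0.00426) and 34 hair follicle regulators (adjusted p = 6.66e-05) lower in black-coated skin, and 17 macrophage and dendritic genes (adjusted p = 9.80e-06), 16 Schwann cell and nerve genes (adjusted p = 0.00426), 28 interferon response genes (adjusted p = 0.00946) and 17 inflammation and antimicrobial genes (adjusted p = 0.00169) higher. With an estimated correlation these adjusted p values were 0.775, 0.750, 0.750, 0.775, 0.775 and 0.323 in that order, and 0 members of the 6 lists passed over their list alone. Without black replicate 1 the hair shaft list was higher in black-coated skin (adjusted p = 6.36e-06), the hair follicle regulators gave 0.642 in the opposite direction, and the macrophage, Schwann cell, interferon and inflammation lists gave 0.739, 0.728, 0.627 and 0.0510. The interferon list gave 0.997 without black replicate 2, 0.0547 without white replicate 5 and 0.184 without white replicate 6, and the Schwann cell list 0.0553 without white replicate 6.

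**Figure D2:**
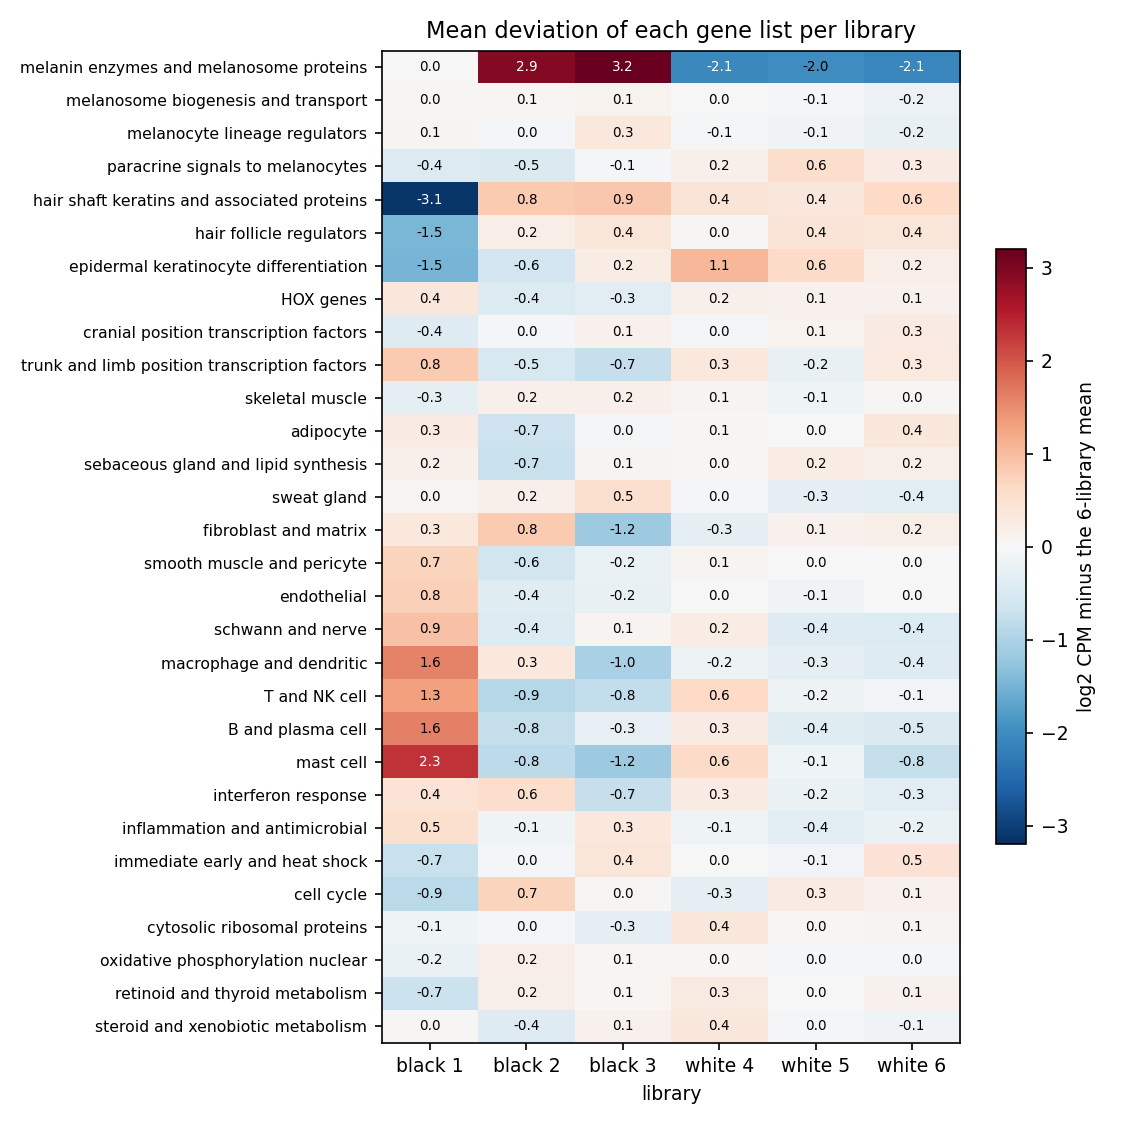
Mean log2 level of each gene list in each library, relative to the mean of the 6 libraries, with the value printed in each cell. The hair shaft list stood at -3.12 in black replicate 1 and the melanin list between -2.08 and -1.98 in the white libraries.

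Position genes were tested because the labels describe animals with a dark head and a pale body, so that coat colour and body site may go together. No other test here could separate colour from site. Of 29 tested HOX genes, 14 cranial and 10 trunk and limb transcription factors, 0 passed over all genes and 0 over their list alone. Relative to the mean of all libraries, the HOX list stood at 0.36, -0.45 and -0.34 log2 units in black replicates 1 to 3. It ran from 0.13 to 0.16 in the white libraries. The trunk and limb list stood at 0.83, -0.52 and -0.73 in black replicates 1 to 3, and from -0.24 to 0.35 in the white libraries. Whether black replicate 1 came from another body site was not tested. Camera placed the HOX genes lower in black-coated skin (adjusted p = 0.0466, median log2 fold change -0.14), with an adjusted p of 0.775 with an estimated correlation, and 18 of the 29 had a lower mean. The cranial and the trunk and limb lists did not pass (adjusted p = 0.621 for each). Without black replicate 1 the HOX genes (adjusted p = 3.76e-05) and the trunk and limb list (0.00344) were both placed lower in black-coated skin, while the HOX genes gave 0.324 without black replicate 2 and 0.367 without black replicate 3. The direction of the trunk and limb list turned without black replicate 3 (0.7055), and that of the cranial list without black replicate 1 (0.294) or white replicate 4 (0.983), 5 (0.248) or 6 (0.347).

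Of the other lists, 75 of 75 cytosolic ribosomal protein genes had a lower mean in black-coated skin (median log2 fold change -0.32, camera adjusted p = 5.13e-11, and 0.750 with an estimated correlation), and the immediate early and heat shock genes were placed lower (adjusted p = 0.0183, and 0.775 with an estimated correlation), but gave 0.404 without white replicate 6 and 0.723 in the opposite direction without black replicate 1. Ribosomal protein and keratin genes have near-identical copies between which reads could be split, so their levels are uncertain. In total 15 of 30 lists passed camera and 0 passed with an estimated correlation. The lists that did not pass were skeletal muscle (adjusted p = 0.451), adipocyte (0.0886), fibroblast and matrix (0.260), smooth muscle and pericyte (0.889), endothelial (0.348), T and NK cell (0.541), B and plasma cell (0.282), mast cell (0.207), cell cycle (0.721), nuclear oxidative phosphorylation (0.451), retinoid and thyroid metabolism (0.282) and steroid and xenobiotic metabolism (0.431). Without black replicate 1 the T and NK cell (2.68e-06), smooth muscle (8.73e-05), mast cell (0.00293), endothelial (0.0117) and adipocyte (0.0443) lists passed as lower in black-coated skin, and the cell cycle (8.03e-05) and oxidative phosphorylation (0.00466) lists as higher. Without black replicate 2 the B and plasma cell (4.59e-04), endothelial (0.0108) and mast cell (0.0201) lists passed as higher and the cell cycle (9.92e-06) and fibroblast (0.0154) lists as lower. In that setting only the white libraries held more than 1 read of the Y-linked LOC108634721, so coat colour and this difference cannot be told apart. The fibroblast (2.99e-07) and mast cell (0.00834) lists passed as higher without black replicate 3, as did the B and plasma cell (0.0133) and mast cell (0.0422) lists without white replicate 4, where the cell cycle list passed as lower (0.0459). The adipocyte list passed as lower without white replicate 5 (0.0451). With all 6 libraries, the camera direction was down while the median and the mean were above 0 for the cranial, smooth muscle and cell cycle lists, while the median alone was above 0 for the trunk and limb and the retinoid lists, and while the mean alone was above 0 for the T and NK cell list.

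Over all 15779 genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes, and 0 of the 2512 genes with a placeholder name. An unadjusted p under 0.05 was reached by 538 genes, 261 higher and 277 lower in black-coated skin, where 789 would be reached by chance. This count depended on the libraries used. It was 1611, 731 and 1154 by edgeR without black replicate 1, 2 or 3, of 16023, 16252 and 16082 genes tested. Without white replicate 4, 5 or 6 it was 463, 333 and 289, of 16026, 16135 and 16215. The 3 black libraries lay all above or all below the 3 white libraries for 1389 genes, 8.80% of those tested, where chance gives 10%. The smallest adjusted p was 0.361, for PLXNC1, a semaphorin receptor, at 26.8 ± 4.61 CPM in black-coated and 5.05 ± 0.838 in white-coated skin (log2 fold change 2.40, SE 0.25). DESeq2 called 78 genes, limma-voom and limma-trend 0, and edgeR without black replicate 1 called 16, 14 of them higher in black-coated skin and 9 of them melanin genes. edgeR called 6 genes without black replicate 2 and 1 without white replicate 4. The 6 came from a fit whose black libraries had next to no Y-linked reads, unlike its white libraries.

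Among genes at an unadjusted p under 0.01 with groups apart and a mean of at least 1 CPM, a choice made after the values were seen, 57 genes were higher and 61 lower in black-coated skin, 44 in each direction with a symbol. Of those with a symbol, the 10 with the largest log2 fold change upward were TYR, TYRP1, MLANA, SLC24A5, TRPM1, PMEL, SLC45A2, PRG4, LTF and MUCL1. PRG4, the joint and tissue lubricant proteoglycan 4, stood at 697 CPM in black replicate 1, 31.9 and 13.1 in the other black libraries and 4.47 ± 1.91 in white-coated skin. The 10 with the largest change downward were ASIP, OSTN, C3H1orf68, KRT10, PRND, FCGBP, LOR, ABHD12B, KRT77 and IL1R2, with log2 fold changes from -5.80 for ASIP to -2.30 for IL1R2. OSTN, the secreted peptide osteocrin, stood at 0.253 ± 0.108 CPM against 4.94 ± 3.72, and IL1R2, a decoy receptor for interleukin 1, at 2.46 ± 1.47 against 12.1 ± 6.85.

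EDNRA, a receptor for endothelins, and the genes next to it, TMEM184C, PRMT9 and ARHGAP10, were lower together in black-coated skin, a group named after its values were seen. EDNRA stood at 64.6 ± 5.28 CPM in black-coated and 106 ± 6.27 in white-coated skin (log2 fold change -0.72, SE 0.15), TMEM184C at 70.5 ± 5.05 against 118 ± 0.891, PRMT9, a protein arginine methyltransferase, at 28.4 ± 2.14 against 54.5 ± 6.83, and ARHGAP10 at 79.1 ± 23.9 against 130 ± 4.59. The groups did not overlap for any of these 4 genes, and 0 of them passed edgeR over all genes, where the smallest adjusted p of the 4 was 0.833.

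**Figure D3:**
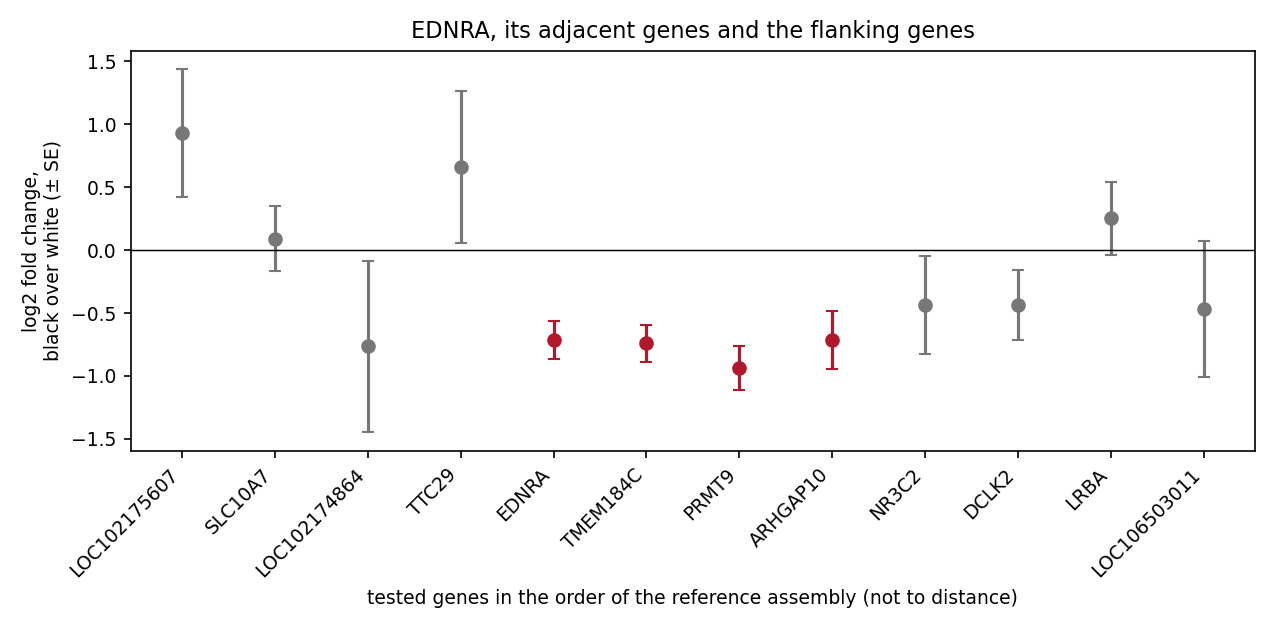
Log2 fold change, black over white, of EDNRA and the genes tested on either side of it, in their order along the goat assembly; points are the fitted values and bars their standard errors. EDNRA, TMEM184C, PRMT9 and ARHGAP10 lie between -0.94 and -0.72, and the 8 flanking genes go both ways, from -0.77 to 0.93, with a median of -0.17. Except for LRBA, the flanking genes had group means of at most 13.9 CPM.

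The libraries were not equally alike. Black replicate 1 had a mean correlation of 0.872 with the other libraries across genes, which are not independent replicates, where the other 5 had means from 0.932 to 0.946. The first principal component held 50.9% of the variance and set black replicate 1 at -116 against 2.82 to 33.9 for the rest. In black replicate 1, 1174 genes lay over 4-fold above or below all other libraries, against 68 to 276 genes in each other library.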

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

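Reads also lay outside the tested genes, above the limit that a count of 0 allows. Transcript rows without a gene name held 20366, 1289 and 17064 reads in black replicates 1, 2 and 3, and 4280, 1876 and 1748 in white replicates 4, 5 and 6. Transfer RNA rows held 2313, 4329 and 5794 reads in black replicates 1, 2 and 3, and 4381, 4551 and 3235 in white replicates 4, 5 and 6. Neither set of rows was compared between the groups.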

How the results depend on the processing

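The limma-voom fit with library quality weights and the fits on the median, mean or single transcript rows were chosen after seeing the data, as was the added hair keratin list; the other settings were planned. Genes called, 0 by edgeR, were 78 by DESeq2 (43 higher, 35 lower in black-coated skin, 21 with a placeholder name, 9 of the melanin list) and 3 with quality weights (PLXNC1, MLANA and PGLYRP1, all 3 higher, 1 of the melanin list). Leaving out each library in turn gave 0 to 16 calls, 0 to 14 higher, 0 to 4 lower, 0 to 6 with a placeholder name and 0 to 9 of the melanin list: 16 without black replicate 1, 6 without black replicate 2 and 1, ASIP, without white replicate 4. DESeq2 and edgeR without black replicate 1 shared 12 genes. The other scalings, filters, thresholds, thinning, glmTreat, limma-voom, limma-trend and transcript rows gave 0 calls, and position genes gave 0 in each setting that refitted all genes. Melanin members passing over the list alone, 9, were 1 by limma-voom and 8 to 13 with a library left out. Epidermal members, 4, were 9 by DESeq2, 1 by limma-trend on log2(FPKM + 1), 1 with quality weights and 1 to 7 with a library left out. Of the 30 lists, 15 passed camera, 0 passed with an estimated correlation, 0 passed by fry, and 10 to 19 passed camera with a library left out. The melanin list had adjusted p values of 0.192 with an estimated correlation and 0.382 by fry, and the epidermal list 0.323 and 0.382; both kept their direction and passed in the other settings. The direction of the named genes' log2 fold changes turned in 0 settings. In other lists 34 list and setting pairs turned direction. For cranial genes these were no filter (adjusted p = 0.268), log2(FPKM + 1) (0.371) and log2(FPKM + 0.1) (0.249); by DESeq2, smooth muscle (0.946), T and NK cell (0.912) and cell cycle (0.955); with quality weights, endothelial (0.0791), B and plasma cell (0.641), mast cell (0.356) and cell cycle (0.106). With a library left out, lists that turned at least once had adjusted p values from 3.86e-06 to 0.0169 (hair shaft), 5.27e-07 to 0.642 (hair follicle regulators), 0.248 to 0.983 (cranial), 0.00344 to 0.866 (trunk and limb), 0.0288 to 0.997 (sebaceous), 2.99e-07 to 0.976 (fibroblast), 8.73e-05 to 0.976 (smooth muscle), 0.0108 to 0.533 (endothelial), 2.68e-06 to 0.616 (T and NK cell), 4.59e-04 to 0.228 (B and plasma cell), 0.00293 to 0.603 (mast cell), 4.10e-05 to 0.723 (immediate early), 9.92e-06 to 0.825 (cell cycle), 0.00466 to 0.831 (oxidative phosphorylation) and 0.160 to 0.976 (steroid), and the added hair keratin list had unadjusted p values from 3.99e-19 to 0.0133. A further 69 pairs lost and 28 gained a list's call without turning. The cause was not tested for any of these changes. No paired analysis was possible because the groups share no replicate numbers. Depth limits the folds of TYR and MLANA, which with 0 white reads are lower bounds at the floor of 3 counts.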

Other observations

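The tests below of black replicate 1, of runs of neighbouring genes and of ASIP were chosen after the results were seen, except the test of scaling for the EDNRA run; the counts over other splits of gene calls, melanin genes and lists were planned.

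Black replicate 1 differed from the other libraries in more than pigment. COL6A5, a chain of collagen VI, stood at 6547 CPM there against 38.8 ± 47.2 (SD) in the other 5 libraries, a 169-fold ratio, and PRG4 at 697 CPM against 11.7 ± 11.98. KRT71, a keratin of the inner root sheath, stood at 329 CPM against 5511 to 7556. Without this library, edgeR also called SLC24A4, an exchanger related to SLC24A5, higher in black-coated skin (log2 fold change 7.06, adjusted p = 0.0267) and the carboxylesterase CES4A lower (log2 fold change -3.26, adjusted p = 0.00472).

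Reads of genes linked to sex chromosomes followed the groups in part, since the 3 white libraries and black replicate 2 were alike and black replicates 1 and 3 differed from them. LOC108634720, described as a zinc finger Y-chromosomal protein, had 0, 223 and 0 reads in black replicates 1, 2 and 3 and 358, 456 and 399 in white replicates 4, 5 and 6. LOC108634721, described as a Y-linked initiation factor subunit, had 1, 688 and 0 reads against 934, 801 and 767. LOC102169084, a noncoding gene on the X chromosome of the ARS1.2 assembly, had 6325, 3 and 5970 reads against 1, 1 and 0. Of the 6 genes that edgeR called without black replicate 2, these are 3. LOC108634550, described as probable ubiquitin hydrolase FAF-X (log2 fold change -9.35), and LOC108634620, described as DDX3X-like (-9.74), were also among them. In that setting the black libraries had next to no Y-linked reads and the white libraries held them. Coat colour and this difference cannot be told apart there. TYRP1 stood at 269 CPM in black replicate 2 and 357 in black replicate 3, so its high level was seen with and without Y-linked reads.

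The 9 melanin genes that passed over their list alone were far lower in black replicate 1 than in the other black libraries, from 2.43% of their mean for GPR143 to 13.9% for MLANA, while of the other 5 tested SLC7A11 stood at 4.08%, GPNMB at 27.01%, OCA2 at 65.3%, BACE2 at 143% and QPCT at 172%. With libraries thinned to equal totals, the median log2 ratio of the 9 genes was -4.07 (SD 0.872). Thinning leaves CPM unchanged on average, and the 9 genes were chosen in these same data, so the thinned value does not decide on depth. The 5 melanin genes with at most 10 reads in white replicates 5 and 6 summed to 21.1 CPM (297 reads) in black replicate 1. They summed to 368 and 520 CPM in black replicates 2 and 3. Gene reads numbered 12648764 in black replicate 1 against 16005583 and 22084569, which argues against lower depth for these 5 genes. An exchange with a white library and a white-coated sample under a black label are argued against by melanin genes with at most 10 reads in a pair of white libraries, whose summed level was at most 0.779 CPM in the white library left out of that choice (SD 0.224), at least 21.1 CPM in black replicate 1 and at least 368 CPM in black replicates 2 and 3, although over all 14 genes black replicate 1 lay above all white libraries in only 10. Carry-over from another black library as the only source of these melanin reads is argued against by 5 genes near absent from white-coated skin. Their proportions differed from those in black replicate 2 (chi-square p = 7.08e-34), in black replicate 3 (6.99e-25) and in mixtures of both (largest p = 1.86e-26). MLANA held 15.8% of their reads against 6.47% and 4.64%. The p-values cover counting error only, and black replicates 2 and 3 also differed from each other (TRPM1 8.73% and 15.5%). Carry-over on top of the sample's own pigment RNA was not tested. Less hair-forming follicle in this sample stays open and is a candidate explanation: the hair shaft list lay at a median of -4.21 log2 units (SD 1.26) against black replicates 2 and 3, and 26 of its 28 genes were lowest there; a wrong label with other pigmented skin was not tested.

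EDNRA, TMEM184C, PRMT9 and ARHGAP10, adjacent on the ARS1.2 assembly among tested genes, were 1.64-, 1.67-, 1.92- and 1.64-fold higher in white-coated skin; the window of 4 genes and the unadjusted p of 0.02 that found them were set after the values were seen, and 3 of 15516 windows in 2 runs met them, the other run lying in the epidermal cluster around KPRP. Under 4 other scalings the median of the 4 genes, less the median of all genes, was -0.75 log2 units at its weakest. A change of scaling shifts all genes nearly alike, so this value could hardly move and does not test scaling. More copies of the segment in the white-coated samples and other differences between the samples cannot be told apart by the 8 flanking genes. These had a median of -0.17 but ran from -0.77 (SE 0.68) to 0.93 (SE 0.51). Their group means were at most 13.9 CPM, except for LRBA at 59.4 in black-coated and 49.8 in white-coated skin (log2 fold change 0.25). As background, gains of copies around EDNRA have been linked to white spotting in Boer goats. A difference in copies needs samples from different goats, and the 1 read of both Y-linked genes together in black replicates 1 and 3 sets these apart from the white libraries, but not black replicate 2. Linked regulation was not tested.

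ASIP stood at 52.1 and 56.8 CPM in white replicates 5 and 6 but at 1.02 in white replicate 4. A black-coated sample under a white label is argued against, since 5 melanin genes with at most 10 reads in white replicates 5 and 6 summed to 0.341 CPM in white replicate 4 and to at least 21.1 CPM in each black library, and too few reads is argued against, since the upper 95% limit of ASIP there was 1.62 CPM. The adjacent tested genes RALY, EIF2S2, LOC108637418, AHCY, ITCH and DYNLRB1 did not rise alike. Their median log2 ratio, white replicates 5 and 6 over 4, was 0.32 (SD 0.29) where ASIP had 5.60. This argues against a shared rise only. Reads running on from an adjacent gene that kept its own level cannot be judged from these values. No biological explanation was tested.

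The 6 libraries can be split in 10 ways, too few for a share under 0.05. Of these, 10 gave as many called genes as the real split (0, highest other 1), which a count of 0 fixes in advance. At an unadjusted p under 0.05, 6 gave as many genes (538, highest other 1073, for black replicates 1 and 2 with white replicate 4). Past camera, 6 gave as many lists (15, highest other 18). As many melanin genes over the list alone were given by 1 split, the real one (9, highest other 8, for black replicate 1 with white replicates 4 and 6). As many windows of neighbouring genes were given by 2 splits (3, highest other 4).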
